A study of Ciona robusta with 5 samples.

How the data were processed

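Larvae were dissociated in calcium- and magnesium-free sea water with trypsin and sorted by fluorescence, per the labels' protocols. Bulk RNA was amplified with SMART-Seq v4 and prepared with a NuGEN Ovation kit, and the single-cell library with the 10x Chromium 3' v2 kit, again per the labels' protocols. The submitters' processing notes name Cell Ranger 2.0.0, STAR 2.5.2b, featureCounts and edgeR, without saying which step each served. The deposited bulk table holds raw counts per gene for each of the 4 libraries, with duplicates removed before counting per the file headers. The deposited single-cell matrix holds UMI counts per gene and barcode, unfiltered. The genome build is not given in the sources used here; the gene identifiers carry the KH2013 prefix. Only the bulk table pairs identifiers with names: 11061 of 15231 genes have a name, 3134 of these share it with another gene, and 4170 have none, so a name is a homology label and not proof of identity.

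The fits, the thresholds, the 20 gene lists, the cell type markers and the rule for named genes were written down before the data were examined. TH bulk was compared with Fascin bulk in edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, 13789 genes tested) under R 4.3.3, with group as the only term and a threshold of 0.05 on Benjamini-Hochberg adjusted p. CPM values were computed here from the counts and TMM-scaled library sizes. DESeq2 1.42.0 (Wald test, its own size factors) was the second test named beforehand. Because edgeR called 0 genes (999 higher and 1943 lower at an unadjusted p under 0.05), the use of DESeq2 calls for named genes, list members and the single-cell lists was decided after that result was seen. Alternatives tried were other scalings, other filters, a replicate block, each library left out in turn, and a test against a fold of 1.5. A fit with 1 library in a group takes its spread from the other group.

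Named genes were the 12 higher and the 12 lower in TH cells with the largest fold change among named genes past the DESeq2 threshold, with both TH libraries on the same side of both Fascin libraries and a mean of at least 10 CPM in the higher group, leaving out 6 unnamed genes on the higher side and 7 on the lower side that ranked above the last of them. Up to 4 members of each list, the reporter genes, and the 3 leading named genes of each cluster were added. List members were matched to names without regard to case. Single values of some genes that the rule would name are not reported here. Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01, then an estimated correlation). With an estimated correlation camera works on the residual degrees of freedom, which are few with 2 libraries per group. A list could then hardly pass, so a call lost there says little about the list. The neuropeptide list had 3 measured members, and of the 10 names in the notochord list 0 matched, so neither was tested.

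For the single cells, a barcode was called a cell at 10% of the 99th percentile of the 3000 barcodes with most UMIs (1538 UMIs) and at least 200 genes. Of all UMIs, 37.9% lay in called cells, and barcodes under 300 UMIs served as the measure of free RNA. Scrublet marked 1 of 2428 cells as a doublet, at an automatic threshold of 0.382, so doublets were in effect not removed. Cells were scaled to 10000 UMIs, log-transformed, and clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). A cluster was named with at least 3 markers of a type, each at 50 CPM or more and a log2 ratio of at least 1 over all other cells, unless another type had more markers among its 10 leading genes. Markers of a special neuron type, such as GAD1/2 in cluster 10, did not count against the name neuron-like. Types tied in number were taken in the order of the written lists. The markers and the minimum of 3 were fixed beforehand; these levels, the exception and the order for ties were not, and that a marker must keep its levels without its highest cell was added after the data were examined. Ratios were computed with 10 CPM added, and lists were compared with 10000 random lists matched in 20 expression bins, with 2000 bootstrap draws over genes. Poisson intervals on CPM, like Wilson intervals on shares, cover counting error only.

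The fits were tested on simulated data with 13789 genes, 200 of them changed. With the dispersion fitted here, edgeR recovered 50% of genes changed 4-fold and 97% changed 16-fold, with 12 false calls; DESeq2 recovered 89% and 100%, with 86 false calls. With a dispersion 10 times smaller both recovered 100%, with 23 and 33 false calls. At the fitted dispersion a 4-fold change was thus often missed by edgeR, and DESeq2 calls carried more false ones. The number of libraries was not varied. Simulated genes varied independently, with the same dispersion in both groups. The real Fascin libraries were further apart (Pearson correlation 0.900) than the TH libraries (0.963), and genes of a cell type moved together. The false calls above therefore do not give the error rate of the DESeq2 calls on the real data. The list score found the planted cluster for 20 of 20 simulated lists of 100 genes changed 4-fold.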

Results

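The series profiled fluorescent cells sorted from dissociated larvae of Ciona robusta, an ascidian whose swimming larva carries a small chordate brain. There were 5 libraries. TH bulk (2 libraries) held cells with a TH>GFP reporter, which the labels call DA cells, and Fascin bulk (2 libraries) held cells sorted on Fascin>tagRFP/Unc-67::GFP, which the labels describe as brain plus contaminants. All 4 bulk libraries were made at 24 hours after fertilisation at 18 °C. A single-cell library (1 library, droplet method with molecular barcodes) held Fascin>tagRFP cells at 20 hours. The bulk table listed 15231 genes, with total counts of 27569231 and 30741709 in Fascin 1 and Fascin 2 and of 31430500 and 16325227 in TH 1 and TH 2. The single-cell matrix held 25044375 molecule counts (UMIs) over 316768 barcodes with at least 1 UMI. Bulk levels are CPM on scaled library sizes, given as mean ± SD with n = 2 per group. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Gene names are those paired with gene identifiers in the bulk table; many name a family of homologues, and a name can be carried by several Ciona genes.

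The bulk comparison asked which genes set TH>GFP cells apart from the wider Fascin-sorted population. TH itself, tyrosine hydroxylase, which makes the dopamine precursor L-DOPA, was at 728 and 851 CPM in the TH libraries and at 7.49 and 35.6 CPM in the Fascin libraries, a 36.6-fold difference between means (gene KH2013:KH.C2.252, DESeq2 log2 fold change 5.17 ± 0.69 SE, adjusted p = 2.04e-11). Without Fascin 1 the log2 fold change of TH was 4.44 and without Fascin 2 6.68. Its regulatory DNA gave the reporter, so these values check the labels. Of the 11 measured genes of dopamine and monoamine synthesis, storage and uptake, 4 rose in TH cells by DESeq2, TH among them. DDC, which turns L-DOPA into dopamine, was at 289 ± 92.3 against 59.3 ± 5.44 CPM (KH2013:KH.L20.60). A second gene named DDC (KH2013:KH.C5.346) stood at 17.3 against 33.0 CPM and passed in neither direction. The other 2 were GCH1/2, the first enzyme of the synthesis of the TH cofactor (271 ± 29.7 against 32.1 ± 19.8 CPM), and QDPR, which recycles that cofactor (96.4 against 39.2 CPM). A vesicular transporter gene, SLC18A1/2/3, fell from 205 ± 157 to 22.3 ± 6.25 CPM (DESeq2 adjusted p = 8.41e-06). Its name covers transporters of monoamines and of acetylcholine, and the same gene (KH2013:KH.C1.498) is in the acetylcholine list. The other 6 passed in neither direction. FSCN1/2, the Fascin gene behind the other reporter, was at 199 and 745 CPM in the Fascin libraries against 136 ± 40.4 CPM in TH cells (DESeq2 adjusted p = 0.0383). That DESeq2 call was lost without Fascin 2 (adjusted p = 0.291), TH 1 (0.425) or TH 2 (0.120). Of the 5 calls in the dopamine list, 4 held whichever library was left out. QDPR was lost without TH 1 (DESeq2 adjusted p = 0.408) and without TH 2 (0.345). With edgeR adjusted over the list alone, 5 genes passed, 4 of them higher; over all genes edgeR's smallest adjusted p was 0.127.

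Among named genes higher in TH cells, the largest fold change with all 4 libraries belonged to Ci-pem, a gene known for its localised maternal transcript in ascidian embryos. It was at 558 ± 216 CPM in TH cells against 5.15 ± 1.38 CPM in Fascin cells, a 108-fold difference (KH2013:KH.C1.755, DESeq2 log2 fold change 6.74 ± 0.45 SE, adjusted p = 8.29e-47). Without Fascin 1 the log2 fold change of CLCA1/2/3/4/5/6 (7.47) was above that of Ci-pem (7.03), and without Fascin 2 that of TH (6.68) was above that of Ci-pem (6.47). MXRA7 reached 3639 ± 349 against 227 ± 149 CPM and GLB-13/18/7, named after nematode globins, 481 ± 78.0 against 27.8 ± 22.1 CPM. LPAR1, a lysophosphatidic acid receptor, stood at 211 ± 21.2 against 13.3 ± 11.8 CPM. KDM1B, named after a histone demethylase, was at 524 ± 120 against 29.1 ± 4.69 CPM. Its identifier (KH2013:KH.C2.253) is the number after that of TH. The homeobox gene GSX1/2 (12.9 ± 4.56 against 0.588 ± 0.471 CPM) and the kinase gene RIPK1 (16.5 ± 1.46 against 0.539 ± 0.401 CPM) were lower in level. So were ALS2CR11 (16.3 ± 6.39 against 0.893 ± 0.179 CPM) and PIF1, a helicase gene (26.1 and 84.5 against 1.36 and 1.64 CPM). For 2 of these 12 genes the TH libraries were far apart: CD93 at 90.0 and 10.3 CPM, and CLCA1/2/3/4/5/6 at 1.68 and 22.1 CPM. CD93 was no longer called by DESeq2 without Fascin 1 (adjusted p = 0.134), Fascin 2 (0.0587) or TH 1 (0.250). CLCA1/2/3/4/5/6 had no adjusted p without TH 2. The other 10 were called whichever library was left out, but several folds moved with the Fascin library. Without Fascin 1 and without Fascin 2 the log2 fold change was 3.26 and 5.39 for LPAR1 (3.97 with both), 3.44 and 5.27 for GLB-13/18/7 (4.08) and 3.42 and 4.87 for MXRA7 (3.98). It was 3.77 and 5.62 for GSX1/2 (4.41) and 4.29 and 5.98 for RIPK1 (4.88). That of PIF1 moved with the TH library, to 5.78 without TH 1 and 4.07 without TH 2 (5.17 with both).

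Named genes lower in TH cells included GABRB1, a GABA receptor subunit, at 0.816 ± 0.173 against 97.8 ± 87.1 CPM (DESeq2 log2 fold change -6.92 ± 0.74 SE, adjusted p = 1.46e-17). The 3 genes named TECTA were at 0.403, 1.65 and 1.51 CPM in TH cells against 123, 262 and 238 CPM in Fascin cells. Others were ZP4 (7.27 ± 2.63 against 838 ± 1128 CPM), CUZD1 (0.864 against 119 CPM), COL27A1 (0.0569 against 12.4 CPM), CELSR2 (0.0578 against 15.1 CPM) and TSPAN4/9 (0.359 against 46.0 CPM). RETSAT, a retinol saturase (0.734 against 110 CPM), NCS1, a calcium sensor (0.244 against 45.4 CPM), and Y38C1AB.1/5 (0.228 against 27.0 CPM) complete the 12. In each of these 12 genes Fascin 2 was above Fascin 1. ZP4 stood at 40.4 CPM in Fascin 1 and 1635 in Fascin 2, NCS1 at 0.809 and 89.9. Without Fascin 2 the DESeq2 log2 fold changes of the 3 TECTA genes were -3.65, -2.34 and -2.43 in place of -8.29, -7.33 and -7.33. Those of RETSAT, CUZD1 and ZP4 were -4.22, -3.28 and -2.52 in place of -7.27, -7.13 and -6.87, and those of GABRB1 and TSPAN4/9 -5.48 and -5.09 in place of -6.92 and -7.06. For NCS1 and Y38C1AB.1/5 they were -1.77 and -1.75 in place of -7.57 and -6.89, with no adjusted p from DESeq2. For COL27A1 and CELSR2 they were -6.19 and -7.40 in place of -7.52 and -8.49. These 2 genes had 4 counts or fewer in each TH library, so their folds are rough. Without TH 1 the DESeq2 calls of NCS1 (adjusted p = 0.216) and of 2 TECTA genes (0.181 for both) were lost.

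**Figure D1:**
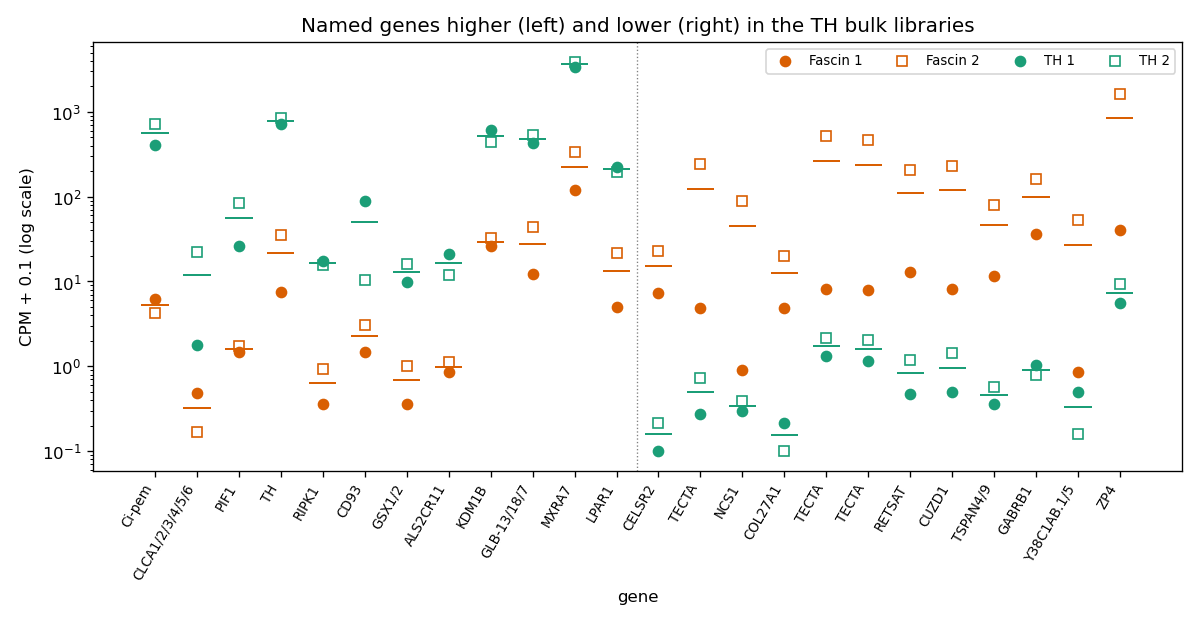
CPM plus 0.1 on a log axis for the 12 named genes higher and the 12 lower in the TH bulk libraries, with 1 point per library and a bar at each group mean. Ci-pem lies at 405 and 711 CPM in the TH libraries, and ZP4 at 40.4 and 1635 CPM in the Fascin libraries.

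Of 10 genes of GABA and glycine neurons, 5 fell in TH cells by DESeq2 and 5 passed in neither direction (5 with edgeR adjusted over the list alone). GAD1/2, which makes GABA, was at 45.7 ± 7.16 against 574 ± 221 CPM, and the vesicular transporter SLC32A1 at 6.24 ± 1.47 against 87.5 ± 37.8. The calls of GAD1/2 and SLC32A1 held whichever library was left out. Of 11 pan-neuronal genes, SYN/1/2/3 of synaptic vesicles rose (341 ± 2.88 against 132 ± 55.9 CPM) and 4 fell, among them CPLX1/2 (34.1 ± 3.07 against 98.9 ± 19.3) and SYT1/9 (2.88 against 22.8). In that list 6 were past the edgeR threshold adjusted over the list alone, and 0 of the 5 calls held whichever library was left out. SYN/1/2/3, for example, was lost without TH 1 (DESeq2 adjusted p = 0.323) and TH 2 (0.356). Of 10 photoreceptor genes, 2 subunits of cyclic nucleotide-gated channels rose, CNGB1/3 (285 ± 59.4 against 57.5 ± 24.9 CPM) and CNGA1/2/3/5 (136 ± 9.54 against 37.4 ± 25.4). Another 4 fell, among them the retinoid handling genes RLBP1 (155 ± 13.8 against 895 ± 452) and RGR (587 ± 123 against 1832 ± 965). Of the list, 6 passed by edgeR adjusted over the list alone, and 2 of the 6 calls, CNGB1/3 and RLBP1, held whichever library was left out.

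Among genes of other neuron types, SLC17A8, a vesicular glutamate transporter, fell (27.6 ± 10.3 against 75.0 ± 32.2 CPM) as the only called gene of 9 in the glutamate list. There edgeR placed 1 gene at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Of 6 acetylcholine genes SLC18A1/2/3 alone fell, also the 1 past edgeR adjusted over the list alone. It is the gene already counted in the dopamine list. Of 9 peripheral sensory neuron genes, TRPV1/4/5/6 rose (44.2 ± 2.09 against 22.1 ± 4.68 CPM) and TRPA1 and a TLX1/2/3 gene fell (0 by edgeR adjusted over the list alone, 3 at an unadjusted p). Of 8 transcription factor genes of coronet or dopaminergic cells, RX1/2/3 rose (15.1 ± 1.02 against 5.71 ± 2.11 CPM) and NR4A1/3 (45.2 ± 4.23 against 145 ± 1.75) and SIX3/4/6 fell, with 1 past edgeR adjusted over the list alone. NKX2-1/4 was at 28.2 ± 4.23 against 31.7 ± 3.64 CPM. Of the 3 measured neuropeptide processing genes PAM, PCSK2 and CPE, DESeq2 called 0 and edgeR placed 0 at an unadjusted p under 0.05. CPE was at 879 ± 178 against 670 ± 414 CPM.

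Some markers of other cell types were also called. Over all genes DESeq2 called 1981 of 13881, with 1557 of them lower. A few calls in this or any other list are thus no sign of a cell type by themselves. Of 7 tested pigment cell genes, 5 fell in TH cells (3 with edgeR adjusted over the list alone). They were the melanin synthesis genes TYRP1 (1.44 ± 1.23 against 128 ± 121 CPM), 2 genes named TYR (3.40 against 74.4 and 3.89 against 227 CPM) and 2 named DCT. The calls of both DCT genes were lost without Fascin 1 (DESeq2 adjusted p = 0.996 and 0.858), which held 82.1 and 33.0 CPM of them against 2.86 and 2.57 CPM in Fascin 2, and without TH 2 (0.0928 and 0.247). Muscle genes separated the Fascin libraries from each other. Over 32 genes the median difference of Fascin 2 from Fascin 1 was -5.07 on the log2 scale. A MYH1/13/2/3/4/6/7/8 gene stood at 4780 CPM in Fascin 1, 19.4 in Fascin 2 and 3283 ± 1510 in TH cells. By that gene the TH libraries held muscle RNA too. Values for TH cells are thus those of a sorted sample that may not have been dopaminergic cells alone. In that list CKM, a creatine kinase gene, rose (72.7 ± 9.87 against 10.4 ± 4.97 CPM), TPM1/2 and MYL1/3/4/6 fell, and 29 passed in neither direction (edgeR 0 adjusted over the list alone, 3 at an unadjusted p under 0.05). Of 6 epidermis genes 3 fell (3 with edgeR adjusted over the list alone), GRHL1/2/3 from 40.2 ± 15.8 to 13.0 ± 2.84 CPM, DLX2/3/5 and SOX15/17/18. Of 23 ependymal, glial or progenitor genes 4 fell, among them SLC1A2, a glutamate transporter (227 ± 78.5 against 794 ± 517 CPM), PAX6 (7.77 ± 4.29 against 38.4 ± 22.9) and NOTCH1/4 (2.20 ± 1.46 against 17.1 ± 3.20). In that list edgeR called 0 adjusted over the list alone and placed 6 at an unadjusted p. Of 14 endoderm and mesenchyme genes, 1 gene named VWF rose, and another VWF, TWIST1 and SOX15/17/18 fell, again 0 by edgeR adjusted over the list alone and 5 at an unadjusted p. SOX15/17/18 (KH2013:KH.C7.407) is the gene already counted in the epidermis list, so its fall does not tell the 2 lists apart.

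Of 21 cilium genes, the dynein arm genes DNAI1 (22.4 ± 6.13 against 6.02 ± 4.43 CPM) and DNAH5/8 (11.9 ± 2.46 against 4.09 ± 0.491) rose, and 19 passed in neither direction (edgeR 0 adjusted over the list alone, 2 at an unadjusted p under 0.05). Of 10 stress genes, HSP90AB1 rose (2563 ± 314 against 1249 ± 28.7 CPM) and HSPA5, an endoplasmic reticulum chaperone, fell (196 ± 16.0 against 596 ± 15.8), with 1 past edgeR adjusted over the list alone. DESeq2 called 0 of 11 cell cycle genes, 0 of 68 ribosomal protein genes and 0 of 53 oxidative phosphorylation genes. Of these edgeR placed 0, 0 and 1 at an unadjusted p under 0.05. MKI67 was at 279 ± 12.9 against 266 ± 51.4 CPM and ATP5B at 405 against 338 CPM. Over all lists, 15 of the 49 genes called by DESeq2 were called whichever library was left out. None of the calls in the pan-neuronal, transcription factor, glutamate, peripheral sensory, epidermis, endoderm and mesenchyme, cilium and stress lists was among these 15, and only 1 of 3 in the muscle list and 1 of 4 in the ependymal, glial or progenitor list were. Of the 49 calls, the number kept was 41, 35, 22 and 19 without Fascin 1, Fascin 2, TH 1 and TH 2.

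As sets, 4 of the 18 lists tested passed camera with a preset correlation of 0.01. GABA and glycine genes (median log2 difference -1.63, adjusted p = 0.000249) and pigment cell genes (-3.86, adjusted p = 0.00857) were lower by camera. Cilium genes (0.57, adjusted p = 0.0499) and oxidative phosphorylation genes (0.21, adjusted p = 0.0499) were higher by camera. None of these camera calls held with an estimated correlation, where the adjusted p was 0.515 for the GABA, pigment and cilium lists and 0.524 for oxidative phosphorylation. For the pigment and cilium lists the estimate (-0.121 and -0.0492) was below the preset, so a higher correlation was not the reason. For the GABA and oxidative phosphorylation lists it was above (0.159 and 0.0283), so a higher correlation may be part of their loss. For muscle and ribosomal protein genes it was 0.556 and 0.904, far above the preset. Camera with an estimate has few residual degrees of freedom here and could hardly pass any list, so these losses do not decide between the lists. At an unadjusted p under 0.05 there were 0 of 18 lists with the estimate and 7 with the preset. The dopamine list had a median of 1.01 and a camera adjusted p of 0.0558 (adjusted p = 0.515 with an estimated correlation). By camera the adjusted p was 1.56e-05 without Fascin 2, 0.0270 without TH 1, 0.0234 without TH 2 and 0.165 without Fascin 1. With an estimated correlation the first 3 were 0.712, 0.719 and 0.683 (camera adjusted p). The GABA and pigment calls held whichever library was left out. The cilium call was lost without Fascin 1 (camera adjusted p = 0.165), Fascin 2 (0.0857) and TH 1 (0.0652) and under upper-quartile scaling (0.0579). The oxidative phosphorylation call was lost without Fascin 1 (camera adjusted p = 0.167), TH 1 (0.0836) and TH 2 (0.0897). The muscle list turned with the Fascin library. It was higher in TH cells without Fascin 1 (camera adjusted p = 4.75e-23) and lower without Fascin 2 (2.41e-05), against an adjusted p of 0.724 with both. Neither muscle call held with the correlation estimated in the same fits (camera adjusted p = 0.772 and 0.712 with an estimated correlation). Without Fascin 2 ribosomal protein genes passed as higher (camera adjusted p = 0.0191), and without Fascin 1 pan-neuronal genes as lower (0.0229). Without TH 1, camera placed epidermis genes as lower (0.0216) and without TH 2 ependymal, glial or progenitor genes as lower (0.0343). With an estimated correlation camera called 0 lists whichever library was left out. The median and the camera direction differed in sign for muscle (-0.19, up), glutamate (0.03, down), peripheral sensory (0.11, down) and ribosomal protein genes (-0.000805, up).

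Over all genes, edgeR's quasi-likelihood test called 0 of 13789 genes higher and 0 lower after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.127. At an unadjusted p under 0.05 it placed 999 genes higher and 1943 lower, where 689 in all would be expected by chance. DESeq2 called 424 genes higher and 1557 lower of 13881. In 57.9% of genes the TH libraries lay on one side of both Fascin libraries, where 4 exchangeable libraries would give 33.3%. Closeness of TH 1 to TH 2 alone would raise that share, so the excess does not by itself show a difference between the groups. TH 1 and TH 2 were closer to each other (Pearson correlation of log2 CPM across genes 0.963) than Fascin 1 and Fascin 2 (0.900). Fascin 1 correlated with TH 1 at 0.906 and Fascin 2 with TH 1 at 0.832; genes are not independent replicates. Without Fascin 1 edgeR called 599 genes higher and 1438 lower, and without Fascin 2 264 and 924. DESeq2 called 1058 higher without Fascin 1, 130 higher and 643 lower without TH 1, and 104 higher and 713 lower without TH 2. Under upper-quartile scaling, which moved the median log2 difference of all genes to 0.17 from 0.03, the share of higher genes among those at an unadjusted p under 0.05 by edgeR was 48.5% in place of 34.0%, and DESeq2 called 623 higher and 1273 lower.

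The single-cell library was used to ask which cell groups make up the Fascin-sorted brain sample. A minimum of 1538 UMIs gave 2428 cells, of which 2427 were clustered into 18 groups, with a median of 2776 UMIs and 1164 genes per cell. Cluster 14 (69 cells, 2.84% of cells, Wilson 95% interval 2.25 to 3.58%) was coronet/dopaminergic-like by 3 of 5 markers, DDC, GCH1/2 and TH. In the same class SLC18A1/2/3 (33.4 CPM against 47.8 in other cells) and the second DDC gene did not pass. Cluster 14 carried 3 neuron markers besides, a tie settled by the order of the written lists. It also carried CNGA1/2/3/5 and a gene named CKM, names that rose in TH bulk among the photoreceptor and muscle genes. Its leading genes were GYC88E, named after a fly guanylyl cyclase (12711 CPM against 39.4 in all other cells), PDE9A, a cyclic GMP phosphodiesterase (31319 against 113), and Ci-R1CiGC29d23 (12391 against 90.3), each with a UMI in 69 of 69 cells. Cluster 10 (99 cells, 4.08%, 3.36 to 4.94%) was neuron-like by 5 markers including SYN/1/2/3 and CPLX1/2, and carried 3 photoreceptor and 3 muscle markers besides. It was led by GAD1/2 (6659 CPM), RH2/3/4/5/6/7 (3506 CPM) and AKAP6. RH2/3/4/5/6/7 had UMIs in 41 of 99 cells, and 24.3% of them came from a single cell. Of the AKAP6 UMIs 70.6% came from a single cell. Cluster 18 (28 cells, 1.15%, 0.799 to 1.66%) was neuron-like by 4 markers and led by HTR3A, a serotonin receptor subunit (595 CPM), FUT3/4/5/6/7/9 and Ci-R1CiGC27a04. Cluster 16 (49 cells, 2.02%, 1.53 to 2.66%) was muscle-like by 14 of 19 markers, with CKM not among them. It was led by K04C1.4, the troponin gene TNNC1 (14832 CPM) and MYL10/2/7. These intervals cover counting error only, and the sort sets what each share is a share of.

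The other 14 clusters stayed unnamed. Clusters 8 and 11 carried 3 photoreceptor markers (RLBP1 and 2 RGR genes), but a marker of another type was among their 10 leading genes: SLC18A1/2/3 in cluster 8 and TNNC1 in cluster 11. Cluster 8 also carried 3 neuron markers (CELF3/4/5/6, SNAP23/24/25 and SYT1/2), a tie. The remaining 12 had fewer than 3 markers of any type, and the genes given below are the first among those with a name. Cluster 1 was the largest (438 cells, 18.0%, 16.6 to 19.6%) and was led by Ci-pem, a claudin gene and CD7, but 1855 of its 1862 Ci-pem UMIs lay in 1 cell. Cluster 2 (298 cells) was led by CG3303, MATN1 and PKD2, cluster 3 (283 cells) by SRPX/2, SUSD4 and T07H6.4, cluster 4 (164 cells) by ITLN3, cluster 5 (151 cells) by NRP1/2, and cluster 6 (136 cells) by GNG10/5. Cluster 7 (125 cells) was led by CAV-1 and a TYR gene with 102 of its 104 UMIs in 1 cell. Cluster 8 (110 cells) was led by the glutamate transporter SLC1A2 (3278 CPM) and GRIN3B, cluster 9 (101 cells) by CES1/2/3, cluster 11 (96 cells) by CRG1 and Gonadoliberin, the gonadotropin-releasing hormone gene (14760 CPM), and cluster 12 (92 cells) by SELP. Cluster 13 (91 cells, 3.75%, 3.06 to 4.58%) was led by ZP4, K02B12.6/9 and Ci-znf054, with UMIs in 16, 19 and 42 of 91 cells. Cluster 15 (63 cells) was led by RSPO3, and cluster 17 (34 cells) by HIS1:CG33807, PODXL and WBSCR27, with 98.1% of the WBSCR27 UMIs in 1 cell. The number of clusters ran from 13 to 27 with the resolution. At resolution 2 a cluster of 73 cells had 3 pigment cell markers (TYR and 2 DCT genes) and was led by them, and another of 42 cells had 4 photoreceptor markers (RLBP1 and 3 RGR genes). The 3 coronet/dopaminergic markers were then in 2 clusters, of 41 and 26 cells, and a cluster of 42 cells led by SLC1A2 had 5 muscle markers besides the muscle-like cluster of 49. Of all UMIs, 52.3% lay in barcodes under 300 UMIs, so free RNA was abundant.

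**Figure D2:**
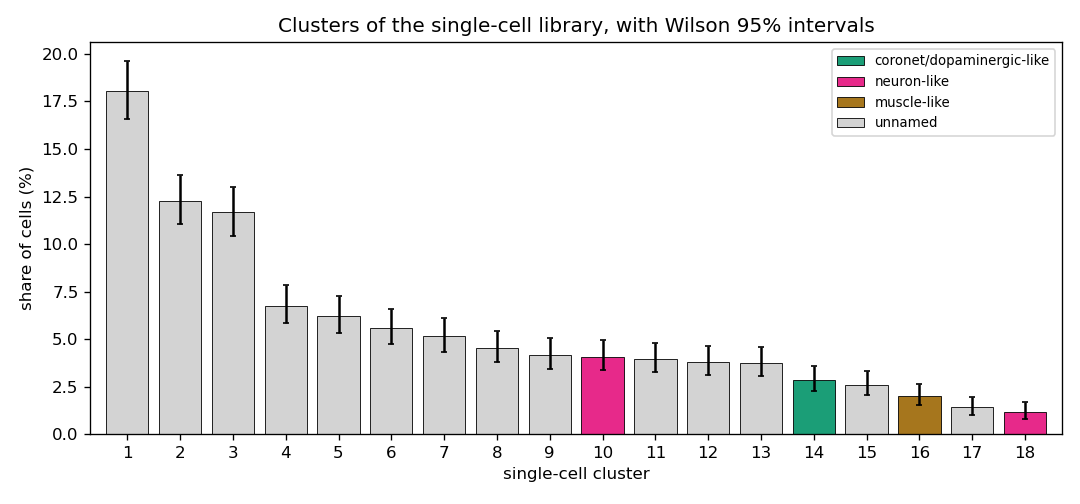
Share of the 2427 clustered cells in each of the 18 single-cell clusters, in percent, with Wilson 95% intervals and colours for the clusters named by markers. The largest share is 18.0% in cluster 1 and the coronet/dopaminergic-like cluster 14 holds 2.84%.

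In cluster 14, TH was at 194 CPM (Poisson 95% interval 147 to 250) with UMIs in 35 of 69 cells, against 8.15 CPM in all other cells and 25.5 CPM in free RNA. No TH UMI was seen in the 49 muscle-like cells, an upper Poisson bound of 23.4 CPM at a median of 2400 UMIs per cell, against 2413 in cluster 14. TH was also present in neuron-like cluster 10 at 126 CPM (92.6 to 167), in 15 of 99 cells. GCH1/2 was at 1155 CPM in cluster 14 (1036 to 1283) against 19.8 in other cells and DDC (KH2013:KH.L20.60) at 107 CPM (73.0 to 151) against 19.0. The second DDC gene had no UMI in cluster 14, an upper Poisson bound of 12.3 CPM, against 21.4 CPM in other cells. Several genes that rose in TH bulk were at their highest in the same cluster: MXRA7 at 10712 CPM against 79.0, GLB-13/18/7 at 1321 against 4.13 and LPAR1 at 547 against 3.91. PTFb, named here after its values were seen, was at 1201 CPM with UMIs in 66 of 69 cells, against 3.26 CPM in other cells, and in bulk at 485 ± 140 against 34.8 ± 32.8 CPM (DESeq2 adjusted p = 6.09e-06). Ci-pem was not at its highest there: it had 1 UMI in cluster 14 (3.34 CPM) against 209 CPM in other cells, nearly all from 1 cell. CD93 and CLCA1/2/3/4/5/6 had too few UMIs to place. CD93 had 1 UMI in cluster 14 (3.34 CPM, against 0.109 CPM in other cells), and CLCA1/2/3/4/5/6 had none in any clustered cell. KDM1B was at 43.4 CPM (23.1 to 74.2) in cluster 14, against 21.7 in other cells, 41.9 CPM (23.9 to 68.0) in cluster 10 and 44.2 CPM in free RNA. FSCN1/2 was at 53.4 CPM (30.5 to 86.7) in cluster 14, below the 155 CPM of free RNA, and at 808 CPM (661 to 977) in neuron-like cluster 18. There was 1 library, so these values have no replicate check.

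The bulk and single-cell data were joined by asking in which clusters the genes that separate TH from Fascin bulk are expressed. The 100 genes with the largest rise in TH bulk were highest in coronet/dopaminergic-like cluster 14. Over the 97 with a UMI, the median log2 ratio of the cluster over all other cells was 2.56 (bootstrap 95% interval over genes 2.08 to 3.22), 77 had a ratio of at least 1, and 78 had their highest level there. The next cluster, neuron-like cluster 10, had a median of -0.09. The 100 genes with the largest fall pointed to cluster 13, the ZP4 and Ci-znf054 cluster, with a median of 3.72 (2.87 to 4.25) over 96 genes, 77 at a ratio of at least 1 and 84 highest there. Both medians lay at percentile 100 of 10000 random lists of the same size matched on expression, a description of this library and not a test across animals. Without Fascin 1, the higher list was highest in muscle-like cluster 16 (median 0.76) and stood at -0.03 in cluster 14. Without Fascin 2, TH 1 or TH 2 it was highest in cluster 14 at 2.73, 2.68 and 2.75. The lists rest on DESeq2 calls, since edgeR called 0 genes (999 higher and 1943 lower at an unadjusted p under 0.05), and the cells were 20 hours old against 24 hours in bulk.

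**Figure D3:**
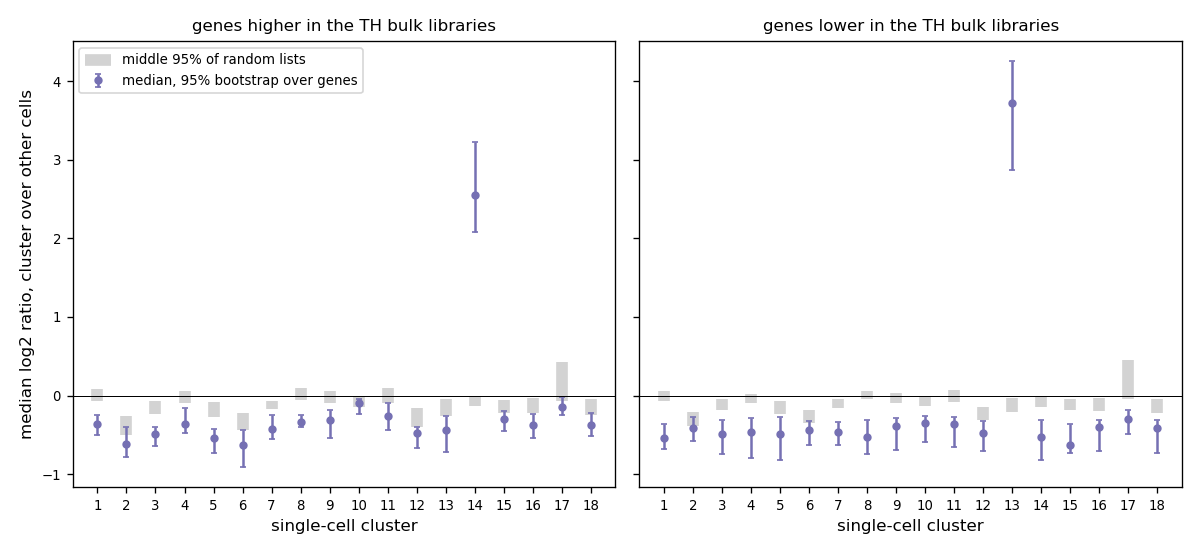
Median log2 ratio of each of the 18 single-cell clusters over all other cells for the 100 genes with the largest rise (left) and the largest fall (right) in TH bulk, with 95% bootstrap intervals over genes and grey bars for the middle 95% of random lists. Cluster 14 stands at 2.56 on the left and cluster 13 at 3.72 on the right.

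Fascin bulk and the sum of the Fascin single cells gave a Spearman correlation of log2 CPM of 0.737 across 14116 genes. TH bulk against the same sum gave 0.750 across 14181 genes. Genes are not independent replicates, and the assay, the age and the sort gate all differ between the Fascin samples, so the value describes these libraries.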

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

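The count of genes called in TH against Fascin bulk depended on the tool and on the libraries. edgeR called 0 in each direction under other scalings and filters and against a fold of 1.5, and with 1 library left out it called 0 to 599 higher and 0 to 1438 lower; DESeq2 called 424 higher and 1557 lower, and 104 to 1058 and 643 to 2023 with 1 library left out. A fit without a Fascin library takes its spread from the TH pair, the closer of the 2 (Pearson correlation 0.963 against 0.900). A fit without a TH library takes it from the Fascin pair. How much of the differences in these counts this gives was not tested. With the replicate number as a block, edgeR called 0 and 0, DESeq2 297 and 1304, and camera 3 lists, with dopamine genes gained (adjusted p = 0.0440) and cilium (0.0769) and oxidative phosphorylation genes (0.0873) lost; with the block and an estimated correlation it called 0 (dopamine genes adjusted p = 0.833 with an estimated correlation). Deviations of same-numbered libraries correlated at -0.0666, and the labels do not say that the number pairs them. Camera called 4 to 6 lists with 1 library left out, and 0 with an estimated correlation, with all libraries and without any 1 of them.

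The largest cluster held 20.0% of cells at resolution 0.5 and 8.74% at resolution 2. Cells numbered 3304, 2771 and 1931 at minima of 500, 1000 and 2000 UMIs, and keeping the 1 marked doublet gave 20 clusters. For genes higher in TH bulk, the median log2 ratio of the highest cluster was 3.54 at resolution 2, 1.89 with 200 genes and 0.76 to 2.75 with 1 library left out; for genes lower it was 2.39 at resolution 2, 2.82 at 1000 UMIs and 2.98 to 3.60 with 1 library left out. The bulk correlation with the single-cell sum was 0.634 for genes with at least 10 counts in both and 0.711 to 0.745 with 1 library left out. Of comparison values, 59 stayed within the range counted as unchanged (1.5-fold for counts, the interval or the spread between replicates for other values) and 26 moved. Calls of single genes were followed here only for the reporter genes and the named genes, which were picked for large folds and separated libraries. With 1 library left out some of these calls were lost, and folds of kept calls often moved. By edgeR in place of DESeq2 all 25 were lost, with the fold in the same direction. They do not stand for DESeq2 calls at large, most of which were lost without TH 1 or TH 2.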

Other observations

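All tests in this part were chosen only after the results were seen. Genes that mark a single-cell cluster (50 per cluster, fewer where not measured) were followed in the bulk libraries. Genes of coronet/dopaminergic-like cluster 14 had a median log2 difference of 3.01 (2.52 to 3.72) between TH and Fascin bulk, and 46 of 50 rose by DESeq2. Genes of cluster 13, led by ZP4 and Ci-znf054, stood at -4.83 (-5.01 to -4.52), and 45 of 49 fell. Genes of cluster 8, led by SLC1A2, stood at -2.05 with 31 lower, and those of neuron-like cluster 10, led by GAD1/2, at -1.44 with 24 lower. Clusters 4 (1.10), 9 (0.74), 1 (0.43) and 17 (0.10) lay on the higher side. Muscle-like cluster 16 was also there at 1.66 (1.01 to 2.09), with 0 genes higher and 4 lower by DESeq2. Its camera direction was down (camera adjusted p = 0.976). The value of 1.66 rests on Fascin 2, where this signature lay at -5.88 relative to Fascin 1. The intervals are over genes only. Camera called 4 of the 18 signatures higher and 12 lower, and 0 with an estimated correlation (smallest camera adjusted p = 0.381). Cluster 14, with 46 of 50 genes higher, was at that same value, so the version with an estimate could hardly call any signature. Signatures were drawn from the same single-cell library, so these values describe the bulk libraries only.

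Ci-pem was 108-fold higher in TH bulk. Depth argued against itself as a cause: TH 1 and Fascin 2 differed 1.02-fold in total counts and 96.9-fold in Ci-pem CPM. A contribution from cells like the 1 barcode with 1855 Ci-pem UMIs among its 3113 could not be told apart from others: of 5 companion genes of that barcode that would have to rise at least 1.5-fold, 4 were at least halfway (HAUS1 at 3.02-fold with 3.50 needed), but ZIC1/2/3 was at 0.801-fold. Transcription in the dopaminergic cells stayed open: cluster 14 held 1 Ci-pem UMI, with an upper Poisson bound of 18.6 CPM against 558 CPM in TH bulk, but age and library type differed.

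The Fascin bulk libraries differed from each other: 818 of 13789 genes were at least 4-fold higher in Fascin 2 and 405 in Fascin 1, against 164 and 205 between TH 2 and TH 1. A depth ratio of 1.12 did not account for the muscle-like signature, which lay at -5.88 (-6.10 to -3.43) in Fascin 2 relative to Fascin 1. The signature of cluster 13 lay at 2.67 (2.48 to 2.88), with 6 signatures higher and 11 lower. The higher ones were those of clusters 8, 10, 11, 13, 14 and 18, which include the neuron-like and the coronet/dopaminergic-like clusters. A different mixture of cell types in the sorts could give these values. A lower share of 1 contaminating type alone was argued against, since 10 signatures besides the muscle-like one also fell. The design gives no biological group within the Fascin libraries, so no biological explanation was tested.

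KDM1B was at 524 ± 120 CPM in TH bulk and 29.1 ± 4.69 CPM in Fascin bulk. In clusters 14, 10, 16 and 18 it was at 43.4, 41.9, 44.5 and 45.7 CPM, and in free RNA at 44.2 CPM. Its identifier, KH2013:KH.C2.253, follows that of TH, KH2013:KH.C2.252, whose regulatory DNA gave the reporter. The cause of the difference between bulk and single cells was not tested.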
